A study of Mus musculus with 6 samples.

How the data were processed

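RNA from mouse fibroblastic and lymph node (LN) stromal cells had been measured on 6 single-colour Affymetrix whole-transcript arrays. The labels gave 4 groups. The first was 1 array of mouse embryonic fibroblasts (MEF) cultured from C57BL/6JJcl embryos between embryonic days 11.5 and 13.5. Another was 1 array of freshly sorted LN stroma from adult C57BL/6JJcl mice, negative for CD45 and CD31 and positive for podoplanin and VCAM-1. The remaining 4 arrays came from 2 LN stromal cell lines of BALB/cA origin, BLS4 and BLS12, each grown with and without a goat polyclonal antibody that activates the lymphotoxin β receptor (LTβR), at 1 µg/ml for 2 days. MEF and LN stroma shared a strain and differed in age, tissue and culture. MEF and the lines were both cultured and differed in strain, tissue and establishment as a line. As MEF were embryonic, they may also have differed in age. LN stroma and the lines differed in strain, culture and establishment as a line. These factors could not be separated within any 1 of the comparisons. Nothing in the labels said that the 2 arrays of a line came from separate derivations. The p-values of single genes here measure only the spread between these samples, which may be technical.

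The deposited values were a linear intensity for each transcript cluster, made by the authors with Affymetrix Expression Console 1.1 according to the submitters' processing notes. The summary and normalization algorithm and the genome build were not given in the sources used here. The design had been written for log2 values and provided for a linear scale, which was found: the lowest intensity was 3.55, so log2 was taken without a floor or pseudocount. The table held 35557 probe set entries, of which 21789 (61.3%) belonged to 1 gene, 1621 to several genes and 12147 to no gene. Of the entries with 1 gene, 21698 were matched by Entrez ID, and 0 symbols needed updating. The entries with 1 gene covered 19938 genes. For the 999 genes with several entries the one with the highest mean over the 6 arrays was used. Values identical to another entry occurred in 701 entries. Entries with several genes or none entered no comparison. Enpp2 and Ccl21a had no entry of their own and were not analysed here. Array data carry no counts, and the number of arrays limits the precision.

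Comparisons, tests, filters, gene lists and alternative settings were chosen before the data were examined, except where the text says otherwise. The antibody response and the difference between the lines came from 1 additive model of cell line and antibody over the 4 cell line arrays. It was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were kept where at least 2 of the 4 arrays lay at or above the array's median, which left 11988. The model had 1 residual degree of freedom, and the moderated spread had 4.59 prior degrees of freedom and a prior SD of 0.151 on the log2 scale. That residual was the disagreement between the antibody differences of BLS4 and BLS12, in which biological and technical parts were not told apart. No repeated array of a line and condition entered any p-value. Beside it stood the genes that differed at least 2-fold in the same direction in both lines. Simulated data with 200 changed genes among 11988 tested the antibody model in 5 runs. It recovered 2% of genes changed by 0.5 log2 units, 52% at 1 unit, 98% at 2 units and 100% at 3 units, and 8.83% of its calls were false. MEF and LN stroma had 1 array each, so their comparisons had no test in the design. Genes were kept where at least 1 array compared lay at or above its median, and those differing by at least 4-fold were counted, in both lines where the lines took part. The overlap of the LN and cell line differences from MEF was set beside independent lists and beside 100 simulations of unchanged groups sharing 1 reference array. Each simulated array varied by the residual spread of the cell line model.

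The 27 gene lists covered the LTβR and NF-κB pathway, chemokines, lymphoid stromal cytokines and receptors, adhesion and stromal surface markers, and the lysophospholipid and sphingolipid axis. They also covered markers of follicular dendritic and marginal reticular cells and of T zone reticular cells, perivascular and contractile genes, interferon-stimulated genes, antigen presentation, complement, collagens and reticular fibre proteins, and matrix proteases and inhibitors. Further lists were cell cycle, Hox genes, imprinted growth genes, skeletal muscle and chondro-osteogenic genes, adipogenic genes, dissociation stress and immediate early genes, cholesterol synthesis, and glycolysis and hypoxia. The last 6 held markers of lymphocytes, myeloid cells, endothelium, epithelium and mesothelium, erythroid cells, and Schwann and neural cells. Lists with at least 5 genes kept were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. The estimated correlation rested on 1 residual degree of freedom. The test that used it had that 1 degree too, and so little power. For the NF-κB pathway under antibody the estimate (-0.042) lay below the preset 0.01, yet the list was not called. Failing with an estimated correlation therefore does not show that correlation made a list's call. With the preset correlation, camera p-values reflect the spread across genes and not between repeated arrays. On simulated data, 50 of 50 lists of 20 genes shifted by 0.5 log2 units were called, and 1 of 1200 unchanged lists. The simulated lists were random and their genes varied independently, so these rates do not cover lists of genes that vary together. In the comparisons without a test, a list's median difference was placed as a percentile among 10000 random lists of equal size and similar intensity. A further 4 lists (pancreatic acinar, salivary gland, mesothelial and other epithelial transcripts) were written after the data had been seen.

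Genes were named by rule. For the antibody these were the 15 largest rises and falls past the threshold with the same sign in both lines; as only 9 genes passed downward, that direction took the 15 largest by the smaller of the 2 lines' differences. For BLS12 against BLS4 the 15 largest each way past the threshold were taken. For the other comparisons they were the 15 largest each way by the smallest difference involved. Up to 6 members of each list with the largest differences were added, and Enpp2, Ccl19, Ccl21a, Cxcl13, Il7, Vcam1, Pdpn, Ltbr, Nfkb2 and Relb in each comparison. The rule allowed the text to give fewer of these, from the top, and the text passes over some higher ranks. Alternatives covered the block for the cell line, the filter, quantile normalization, centring of each array on its median, an intensity trend, the mean of a gene's entries, a fit of all 6 arrays, other fold sizes, leaving out each line in turn, and a limma fit in which the lone arrays were assumed to vary like the lines. Groups of fewer than 3 arrays allowed no counts over other splits. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.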

Results

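The arrays compared stromal cells freshly sorted from LN, 2 LN stromal cell lines with and without LTβR stimulation, and MEF, to assess relative gene expression. LTβR is the receptor through which lymphotoxin acts on stromal cells. MEF and LN stroma had 1 array each and no replicate, and each line had 1 array per condition. Median intensities lay close together, from 51.5 in unstimulated BLS12 to 56.3 in antibody-treated BLS12, and the highest intensities ran from 23018 to 24064. Across all entries, Pearson's r was 0.990 between the BLS4 arrays and 0.982 between the BLS12 arrays. It was 0.964 to 0.973 between the lines, 0.958 to 0.967 between MEF and the lines, and 0.93 to 0.942 between LN stroma and the other arrays. These correlations are across entries, which are not independent replicates. The table held no detection call, so in every comparison the size and rank of a difference are approximate where its lower level lay below the array median. Members of the 27 gene lists were counted only where they passed the intensity filter of the comparison.

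The antibody comparison asked which transcripts changed with the LTβR antibody, with each line as its own control. No group had a control antibody, so effects of the goat antibody that do not run through LTβR were not separated. The largest rise was in Spib, which encodes an Ets-family transcription factor known from B cells, by 3.86 log2 units (SE 0.188, adjusted p = 0.00573, higher in 2 of 2 lines). Mmp9, a gelatinase, rose by 3.56 (SE 0.149, adjusted p = 0.00573), and Cxcl16, a membrane-bound chemokine, rose by 3.14 (SE 0.163, adjusted p = 0.00606). Inhibitors of NF-κB signalling were among the rises: Nfkbie by 2.93 (SE 0.145, adjusted p = 0.00573), Tnfaip3 by 2.36 (SE 0.199, adjusted p = 0.0305) and Nfkbia by 2.00 (SE 0.170, adjusted p = 0.0305). Birc3, an inhibitor of apoptosis in the same pathway, rose by 2.24, Vegfc, a growth factor for lymphatic endothelium, by 2.28, and Rarres2, the chemoattractant chemerin, by 2.12. In the other direction Scg2, a secretory granule protein, fell by 3.13 (SE 0.142, adjusted p = 0.00573), from 10.3 to 7.08 log2 intensity in BLS4 and from 8.84 to 5.79 in BLS12.

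In all, 33 of 11988 genes passed the threshold in limma, 24 higher and 9 lower with antibody, and 1396 had an unadjusted p under 0.05. All 33 had the same sign and at least a 2-fold difference in both lines. Further rises were in Dram1 (1.86), Rrad (1.86), Dclk1 (1.85), Angptl4 (1.79), and the chemokines Ccl7 (1.74, SE 0.181) and Cxcl10 (1.70, SE 0.143). Besides Scg2, the falls were in Emb (-2.63, SE 0.276), Ogn (-2.10), a small proteoglycan of the matrix, Cav1 (-1.82), the main protein of caveolae, Sfrp2 (-1.78), a secreted modulator of Wnt signalling, Aoc3 (-1.58), Cnn1 (-1.49), which encodes calponin, Kcne4 (-1.41) and Ctla2a (-1.41). Several genes with large differences missed the threshold. Lox, the matrix cross-linking enzyme, had a difference of -2.14 (adjusted p = 0.0941), Hes1, a target of Notch signalling, -1.71 (adjusted p = 0.0798), Npr3 -1.71, Pappa -1.45, Atp10a -1.31 and Fzd4 -1.21.

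Among the genes followed in each comparison, Nfkb2 differed by 1.96 (adjusted p = 0.0527) and Relb by 1.09 (adjusted p = 0.0918); both encode subunits of the non-canonical NF-κB dimer. Vcam1 differed by 0.54 (adjusted p = 0.306), Ccl19 by 0.28 (adjusted p = 0.522), Pdpn by 0.34 (adjusted p = 0.571) and Ltbr by -0.16 (adjusted p = 0.719). None of these 6 passed in limma. Cxcl13, the B cell zone chemokine, and Il7, a survival factor for lymphocytes, were below the filter and not tested. Cxcl13 went from 4.69 to 4.77 log2 intensity in BLS4 and from 5.11 to 6.14 in BLS12, and Il7 from 3.89 to 4.25 and from 4.10 to 5.40. The median of the antibody-treated array lay above that of the unstimulated one by 0.13 log2 units in BLS12 and by 0.02 in BLS4, and whether scaling or the antibody made this difference was not tested. With each array centred on its median 98 genes passed (54 higher, 44 lower, all 33 retained), after quantile normalization 6 (5 higher, 1 lower, all 6 among the 33), and without the cell line as a block 0.

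**Figure D1:**
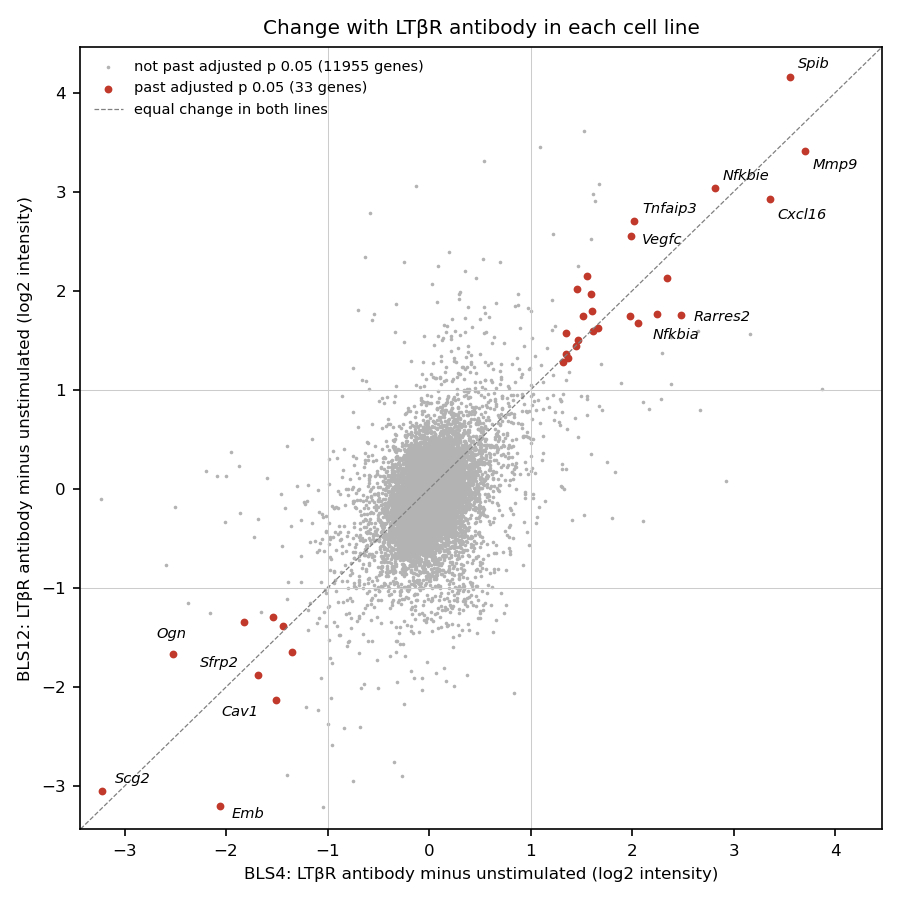
Antibody-treated minus unstimulated log2 intensity in BLS4 (horizontal) and in BLS12 (vertical) for 11988 genes, 1 point per gene. The 33 genes past an adjusted p of 0.05 are in red, from Spib at 3.86 to Scg2 at -3.13 on average, the other 11955 are in grey, and the dashed line marks equal differences.

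Of 20 tested members of the LTβR and NF-κB pathway (21 with an entry), 5 rose, 0 fell and 15 did not pass, and 14 rose and 0 fell when adjusted over the list alone. The list moved up against the other genes (camera adjusted p = 1.9e-15, median 0.94 log2 units, 17 members positive), with an adjusted p = 0.625 with an estimated correlation. The rises were in Nfkbie, Tnfaip3, Birc3, Nfkbia and Tnip1 (1.63), and Birc2 differed by 2.06 (adjusted p = 0.0528). Chemokines, which attract leukocytes, had 14 tested members of 30 with an entry: 3 rose (Cxcl16, Ccl7 and Cxcl10), 0 fell and 11 did not pass, and 8 rose and 0 fell when adjusted over the list alone. Their median was 1.1 (camera adjusted p = 1.59e-10), with an adjusted p = 0.625 with an estimated correlation. Ccl2 differed by 2.37 (adjusted p = 0.0798), Ccl9 by 2.27 (adjusted p = 0.0747), and Ccl11 by 2.93 in BLS4 and 0.08 in BLS12. Antigen presentation covers the immunoproteasome and MHC loading. Its 11 members all had positive differences averaged over the lines, with 10 positive in BLS4 and 11 in BLS12. Of them 1 rose (Cd74, the MHC class II invariant chain, by 1.47), 0 fell and 10 did not pass. Adjusted over the list alone, 7 rose and 0 fell (camera adjusted p = 8.78e-09), with an adjusted p = 0.625 with an estimated correlation. The immunoproteasome subunits Psmb8 and Psmb10 differed by 1.56 (adjusted p = 0.0709) and 1.28 (adjusted p = 0.0518).

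Enzymes and regulators of cholesterol synthesis had negative differences averaged over the lines in all 17 tested members, with a median of -0.67. By line, 0 were positive in BLS4 and 1 in BLS12. In limma 0 of the 17 passed over all genes, and 14 fell and 0 rose when adjusted over the list alone. The list moved down (camera adjusted p = 1.23e-11), with an adjusted p = 0.625 with an estimated correlation. Idi1 differed by -1.18 (adjusted p = 0.0931), Cyp51 by -1.14 (adjusted p = 0.0856) and Hmgcs1 by -0.81 (adjusted p = 0.151). Of 33 collagens and reticular fibre proteins, the scaffold of the LN, 1 fell (Ogn), 0 rose and 32 did not pass, and 11 fell and 1 rose when adjusted over the list alone. Their median was -0.35 (camera adjusted p = 8.17e-07), with an adjusted p = 0.625 with an estimated correlation, and Col3a1 differed by -1.1 (adjusted p = 0.0735). Of 14 perivascular and contractile genes, 1 fell (Cnn1), 0 rose and 13 did not pass, and 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0288), with an adjusted p = 0.625 with an estimated correlation.

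In 7 T zone reticular cell markers all differences averaged over the lines were positive (median 0.28), with 6 positive in each line. None passed over all genes in limma. Adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.00242), with an adjusted p = 0.625 with an estimated correlation. Grem1 differed by 2.16 in BLS4 and 0.81 in BLS12, and Ch25h, the enzyme making 25-hydroxycholesterol, by 2.67 and 0.80. Complement had 11 members with a median of 0.41, of which 0 passed over all genes, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00621), with an adjusted p = 0.625 with an estimated correlation. Cfb, complement factor B, differed by 2.57 (adjusted p = 0.12). Camera called 8 lists, 5 up and 3 down, and fry called 1, the NF-κB pathway (adjusted p = 0.0429). The same 8 were called, in the same directions, after quantile normalization and, among 11 in all, after centring; these list counts were chosen after seeing the data.

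**Figure D2:**
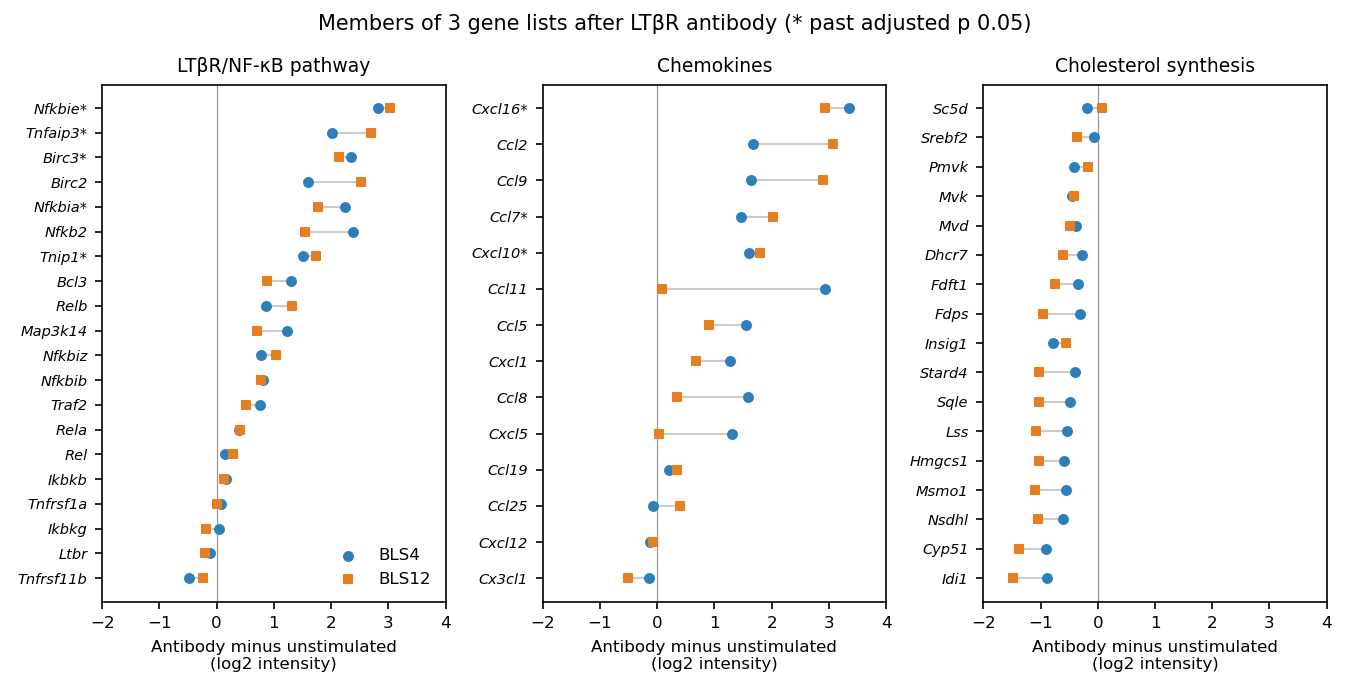
Antibody-treated minus unstimulated log2 intensity of members of the NF-κB, chemokine and cholesterol synthesis lists, 1 point per gene and line, with an asterisk at genes past an adjusted p of 0.05. The list medians of the 2 lines' mean differences were 0.94, 1.1 and -0.67.

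The other lists tested did not pass in camera. Lymphoid stromal cytokines and receptors had 16 members, with 1 rise (Vegfc) and 2 rises and 3 falls when adjusted over the list alone (camera adjusted p = 0.105, and adjusted p = 0.625 with an estimated correlation). Matrix proteases and inhibitors had 17, with 1 rise (Mmp9) and 3 rises and 3 falls when adjusted over the list alone (camera adjusted p = 0.283), and camera and fry gave this list opposite directions. Adhesion and stromal surface markers had 17 members, 0 past the threshold in limma, and 2 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.129); Madcam1 differed by 1.40 (adjusted p = 0.0923). The 16 members of the lysophospholipid and sphingolipid axis had 0 calls, and 2 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.0539). Follicular dendritic and marginal reticular cell markers (8) had 3 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.39), and interferon-stimulated genes (19) had 3 rises and 1 fall on the same basis (camera adjusted p = 0.343). Cell cycle genes (34) had 0 calls in limma on either basis (camera adjusted p = 0.0676). Camera adjusted p values were 0.343 for dissociation stress genes (25), 0.3 for glycolysis and hypoxia (17), 0.574 for adipogenic genes (7, with a median of 0.20, a mean of -0.01 and direction up), 0.279 for imprinted growth genes (8), 0.672 for Hox genes (25), 0.343 for skeletal muscle and chondro-osteogenic genes (9), 0.428 for endothelial markers (6) and 0.672 for epithelial and mesothelial markers (10). No member of these last 8 lists passed over all genes in limma, and adjusted over the list alone 2 stress genes rose and 1 fell, 1 adipogenic gene (Lpl) and 1 endothelial gene (Kdr) fell, and no other did. Medians of the stress, glycolysis and interferon lists were 0.05, 0.05 and 0.07 and became negative after centring, the interferon list also after quantile normalization.

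By size alone, 80 genes differed at least 2-fold in the same direction in both lines, 52 higher and 28 lower, where unrelated lines would share 1.86 and 1.53. Of genes at least 2-fold apart in both lines, 0 had opposite signs. BLS12 had more such genes than BLS4: 447 (192 higher, 255 lower) against 188 (116 higher, 72 lower). S1pr3, a sphingosine-1-phosphate receptor, differed by 3.45 in BLS12 and 1.09 in BLS4. Across genes the differences of the lines correlated with Pearson's r of 0.426 and Spearman's rho of 0.327; genes are not independent replicates. Their SD was 0.317 in BLS4 and 0.438 in BLS12. Without BLS4 447 genes passed the size, and without BLS12 188.

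The comparison of BLS12 with BLS4 described how the 2 LN stromal lines differed from each other. BLS12 had higher levels of Gpm6a, a membrane glycoprotein, by 6.19 log2 units (SE 0.492, adjusted p = 0.00157), of the transcription factor Nfib by 5.55, of Igfbp4, an insulin-like growth factor binding protein, by 5.5 (SE 0.141, adjusted p = 0.000249), and of Eng, the TGF-β coreceptor endoglin, by 4.13 (adjusted p = 0.000296). BLS4 had higher levels of Postn, a matricellular protein, with a BLS12 minus BLS4 difference of -5.75 (SE 0.161, adjusted p = 0.000249). Also higher in BLS4 were Rspo2, which potentiates Wnt signalling (-5.62), Mmp2, a gelatinase (-4.83, SE 0.197, adjusted p = 0.000491), the chemokine Ccl8 (-4.73, SE 0.296, adjusted p = 0.000867), and Lgr5, an R-spondin receptor (-4.45). Other transcripts higher in BLS12 were Ces2g (5.36), Plac8 (5.17), Vat1l (4.92), Pkhd1l1 (4.90), Bnc1 (4.61) and Cd55 (4.07), a complement regulator. Unstimulated BLS4 lay below its array median of 5.74 in most of these, as Gpm6a at 4.47 and Nfib at 4.34, so their sizes and order are approximate. Higher in BLS4 were also Ms4a4d (-5.31), Srpx2 (-5.06), Gpx3 (-4.92), Dpt (-4.22) and Thbs2 (-4.22).

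In limma 2835 of the 11988 genes (23.6%) differed between the lines, 1467 higher in BLS12 and 1368 higher in BLS4, and 129 and 161 of them by at least 4-fold. Line differences in unstimulated and in antibody-treated cells correlated across genes with r of 0.848. Vcam1 was higher in BLS12 by 0.90 (adjusted p = 0.0162), while Pdpn (-0.20, adjusted p = 0.506), Ltbr (-0.08, adjusted p = 0.725), Ccl19 (0.07, adjusted p = 0.744), Relb (0.39, adjusted p = 0.148) and Nfkb2 (0.81, adjusted p = 0.0523) did not pass. Without the antibody as a block 1428 genes passed, all of them among the 2835. More of these were higher in BLS4 (758) than in BLS12 (670), as after quantile normalization (1483 and 1308), so the larger number in BLS12 depended on the setting.

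Cell cycle genes (34 tested of 35 with an entry) had higher levels in BLS12 in all 34 when averaged over both conditions, with a median of 1.14 log2 units. Taken apart, a split chosen after seeing the data, the median was 1.71 in unstimulated cells (34 positive) and 0.45 in antibody-treated cells (30 positive). Of these 16 passed over all genes and 27 when adjusted over the list alone (camera adjusted p = 2.12e-08), with an adjusted p = 0.889 with an estimated correlation. Kif11 differed by 2.22 (3.09 unstimulated, 1.34 with antibody), Top2a by 2.16 (3.01 and 1.31) and the proliferation marker Mki67 by 1.49. Of 14 chemokines 8 were higher in BLS4, 0 in BLS12 and 6 did not pass, and 9 were higher in BLS4 when adjusted over the list alone (camera adjusted p = 0.000454), with an adjusted p = 0.708 with an estimated correlation. Ccl11, an eosinophil attractant, differed by -4.02 (SE 0.618), from -2.60 in unstimulated to -5.44 in antibody-treated cells, Cxcl5 by -2.85 and Cxcl12 by -2.17. Glycolysis and hypoxia genes had 9 of 17 members higher in BLS4 and 1 in BLS12, with 12 and 1 when adjusted over the list alone (camera adjusted p = 0.001), and Adm differed by -2.92 and Egln3 by -2.65. The list had an adjusted p = 0.708 with an estimated correlation. Interferon-stimulated genes had 9 of 19 members higher in BLS4 and 0 in BLS12, with 10 and 0 when adjusted over the list alone (camera adjusted p = 0.00278), and Ifit3 differed by -2.26 and Ifit1 by -2.12. This list too had an adjusted p = 0.708 with an estimated correlation.

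Adipogenic genes had 5 of 7 members higher in BLS4, also when adjusted over the list alone, with Pparg, the master regulator of adipogenesis, at -1.91 (camera adjusted p = 0.00378, and adjusted p = 0.708 with an estimated correlation). Matrix proteases and inhibitors had 10 of 17 members higher in BLS4 and 4 in BLS12, with 12 and 5 when adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.708 with an estimated correlation). Among them Mmp3 (2.89) and Timp3 (3.01) were higher in BLS12. Dissociation stress genes had 8 of 25 higher in BLS4 and 2 in BLS12 on both bases, over all genes and adjusted over the list alone (camera adjusted p = 0.0317, and adjusted p = 0.708 with an estimated correlation). Of 10 epithelial and mesothelial markers 5 were higher in BLS12 and 0 in BLS4, also when adjusted over the list alone (camera adjusted p = 0.0309, and adjusted p = 0.708 with an estimated correlation). These were Upk3b (3.06), Msln (1.90), Upk1b (1.86), Krt19 (1.34) and Wt1 (0.56), all known from mesothelium. None of these 8 lists passed in fry, where the lowest adjusted p was 0.0847.

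Some lists that camera did not call held large differences in both directions, while cholesterol synthesis (3 of 17) and antigen presentation (1 of 11) had calls only toward BLS4. Collagens and reticular fibre proteins had 9 of 33 members higher in BLS12 and 10 in BLS4, and 9 and 12 when adjusted over the list alone (camera adjusted p = 0.904), with Fmod at 3.96 and Dcn at 3.27 against Postn and Col6a3 (-3.03). Lymphoid stromal cytokines had 4 of 16 higher in BLS12 and 5 in BLS4, and 5 and 6 when adjusted over the list alone (camera adjusted p = 0.904), with Il33 at 2.36 and Kitl, the ligand of Kit, at 2.06 against Hgf at -2.44. Adhesion markers had 7 of 17 higher in BLS12 and 3 in BLS4, the same when adjusted over the list alone (camera adjusted p = 0.135), with Icam1 at 2.46 and Pdgfrb at -1.91. Complement had 4 of 11 higher in BLS12 and 3 in BLS4, and 4 and 4 when adjusted over the list alone (camera adjusted p = 0.875), with Cd59a at 3.05 and Masp1 at -3.85. Peg3 (3.17) and Itga7 (3.26) were higher in BLS12, as was Clu, a follicular dendritic cell marker (3.94). Median, mean and test differed in sign for some of these lists. Complement had a median of -0.06 and a mean of 0.35 with camera up, and collagens (0.03 and 0.00) and cytokines (0.05 and 0.02) had camera down. Imprinted growth genes (-0.25 and 0.35) and perivascular genes (-0.14 and 0.14) had camera down and fry up, as did muscle genes and T zone markers, whose medians and means were negative. Medians of collagens and cytokines became negative after quantile normalization (-0.10 and -0.04).

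**Figure D3:**
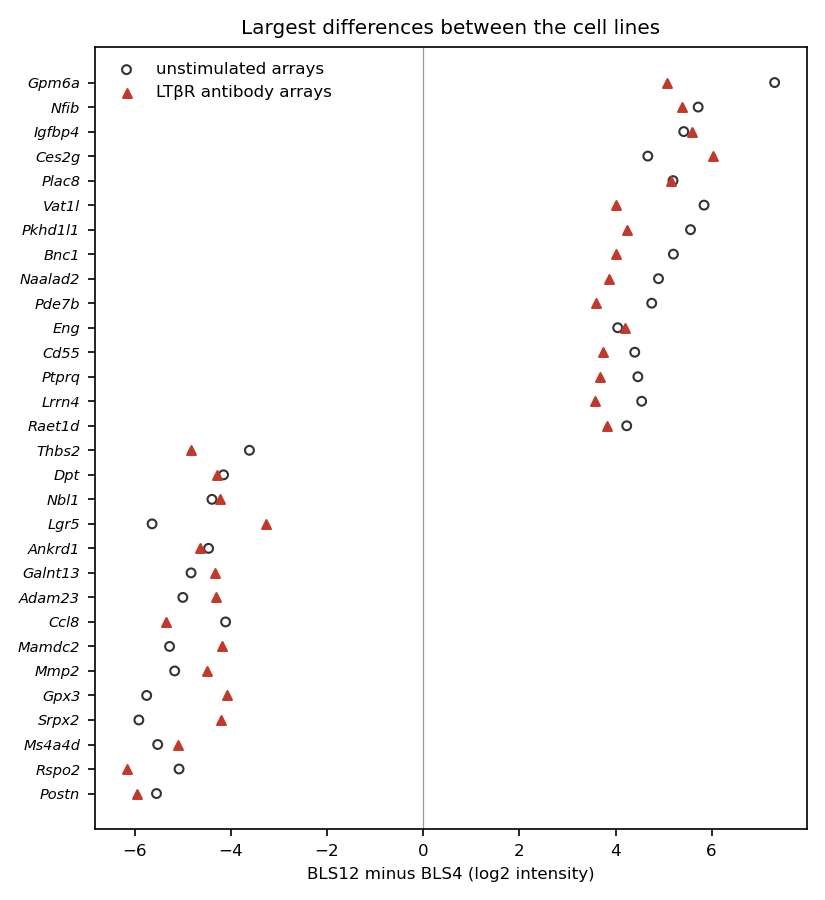
BLS12 minus BLS4 difference in log2 intensity for the 15 genes with the largest differences in each direction, with open circles for unstimulated and red triangles for antibody-treated arrays. Averaged over both conditions, the differences run from 6.19 for Gpm6a to -5.75 for Postn.

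LN stroma was set against MEF to show what adult LN stroma expressed relative to embryonic fibroblasts. Cxcl13, the B cell zone chemokine, stood at 12.82 log2 intensity in LN stroma and 4.64 in MEF, and Ccl19, the T zone chemokine, at 12.49 and 6.08. The cytokines Il6 (11.94 against 4.14), Il33 (11.61 against 4.80) and Il7 (9.13 against 5.44) were also higher in LN stroma, as were the leptin receptor Lepr (7.78 log2 units), complement C7 (7.88) and C4b (7.21), and the methyltransferase Inmt (7.91). In MEF these last 4 stood at 3.98, 3.77, 5.16 and 4.55, below the array median of 5.74 and without a detection call, so the sizes and order of their differences are approximate. MEF had higher levels of Sema3a, with an LN stroma minus MEF difference of -5.56, and of Ano3 (-5.09), Prrg4 (-4.82) and Ddah1 (-4.81). Lower in this ranking came the retinoic acid binding protein Crabp1 (-4.55), Hmga2 (-4.36), Igfbp2 (-4.32) and the fetal growth factor Igf2 (-4.28). Of 12613 genes 585 were at least 4-fold higher and 370 at least 4-fold lower in LN stroma, while at 2-fold more were lower (1523) than higher (1292).

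Immediate early and dissociation stress genes, which tissue digestion is known to induce, were among the largest differences: 21 of 25 were at least 4-fold higher in LN stroma, with a median of 3.41 (percentile 100 among random lists). Fosb stood at 13.29 against 6.06 and Fos at 12.48 against 6.53. Beside them, chemokines had 13 of 20 members 4-fold higher (median 3.75, percentile 100), T zone reticular cell markers 6 of 10 (3.68, 100), and lymphoid stromal cytokines 10 of 19 (2.45, 100). Complement had 7 of 14 higher and 3 lower (2.72, 100), antigen presentation 6 of 15 higher (1.97, 100), interferon-stimulated genes 9 of 20 (1.70, 100), and follicular dendritic and marginal reticular cell markers 4 of 10 (1.55, 99.99). In the NF-κB pathway 7 of 21 were higher and 1 lower (1.30, 100), with Nfkbia at 12.83 against 8.43, Nfkb2 at 9.84 against 8.53 and Relb at 8.64 against 7.42. Collagens and reticular fibre proteins had 11 of 35 higher and 4 lower (0.75, 100), with the proteoglycan Lum at 12.01 against 5.43. Vcam1 stood at 11.9 against 9.96, and Pdpn (10.2 against 10.42) and Ltbr (8.25 against 8.33) lay close together.

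Cell cycle genes were lower in LN stroma, 19 of 35 by at least 4-fold (median -2.07, percentile 0.0), with Bub1 at 3.88 against 8.07. Perivascular and contractile genes had 7 of 16 lower and 3 higher (-1.96, 0.0): Cnn1 was at 6.15 against 10.20, while Rgs5, a pericyte marker, was at 11.30 against 6.62. Imprinted growth genes had 4 of 12 lower (-1.53, 0.0), and cholesterol synthesis 1 of 17 (-1.13, 0.01). Markers of other cell types also differed. Myeloid markers had 4 of 14 lower in LN stroma and 1 higher (-1.54, 0.0), with lysozyme Lyz2 at 10.36 in MEF and 5.73 in LN stroma. Schwann and neural markers had 2 of 6 lower (-1.60, 0.03), with nestin (Nes) at 9.17 in MEF and 5.03 in LN stroma. Endothelial markers had 4 of 15 higher (0.64, 99.81), among them Sele (8.90 against 5.55), Glycam1 (7.34 against 4.66) and Plvap (7.68 against 5.20). The erythroid list had 2 measured genes, with Alas2 at 6.21 against 5.22 and Slc4a1 at 6.26 against 5.91. Adhesion markers (4 of 18 higher, 2 lower, median 0.70), adipogenic genes (3 of 8 higher, 1.18) and matrix proteases (2 of 18 higher, 0.33) had percentiles of 100, 99.9 and 99.69. Hox genes, glycolysis, muscle, epithelial and lysophospholipid lists had percentiles of 44.45, 21.28, 18.47, 17.44 and 68.52, the last with a median of -0.10 that changed sign after quantile normalization.

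Transcripts of secretory glands were also high in LN stroma: Bpifa2, a salivary protein, stood at 11.84 and the amylase Amy1 at 10.55, against 4.23 and 3.43 in MEF. Without the pancreatic and salivary gland transcripts, a setting chosen after seeing the data, 560 genes were 4-fold higher and 370 lower.

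**Figure D4:**
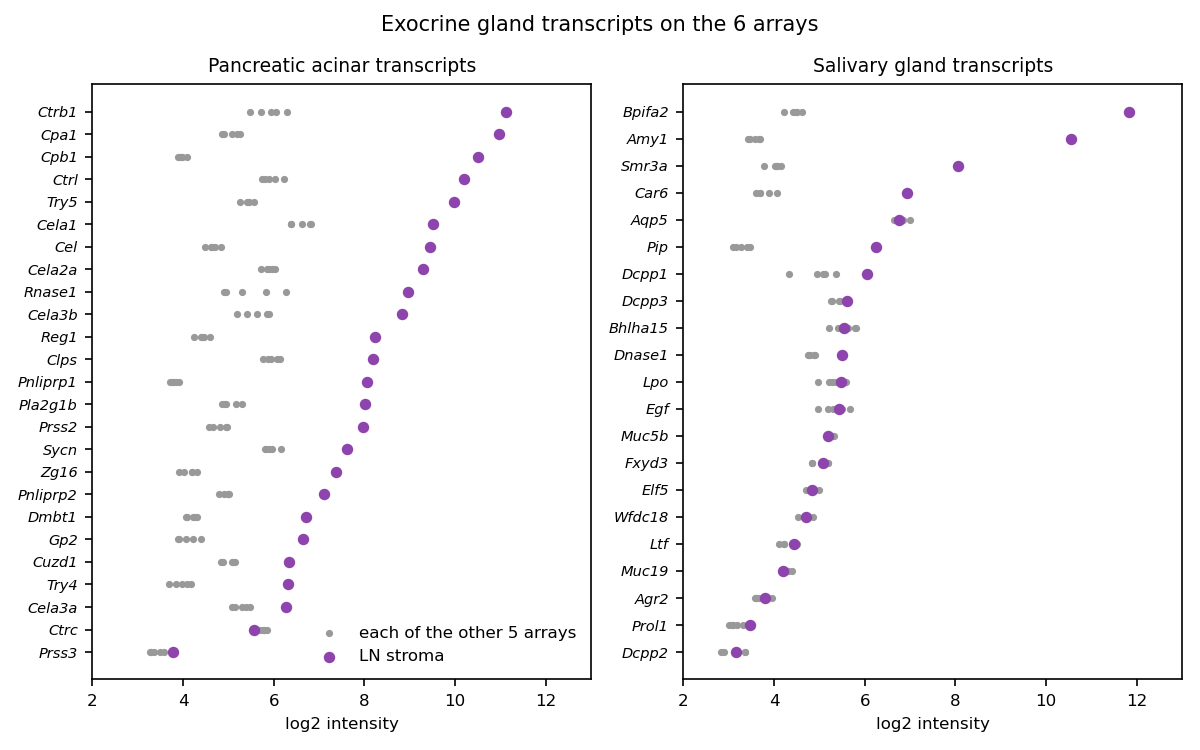
Log2 intensity of 25 pancreatic acinar and 21 salivary gland transcripts in LN stroma (purple) and in the other 5 arrays (grey), 1 point per array. Ctrb1 reached 11.13 and Bpifa2 11.84 in LN stroma, while Aqp5 was at 6.76.

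Unstimulated lines were set against MEF to show how the LN stromal lines differed from embryonic fibroblasts in culture. Both lines had higher levels of Xdh, xanthine dehydrogenase, by at least 5.38 log2 units, of lipoprotein lipase Lpl by at least 4.63, of the complement proteases C1s1 (4.18) and C1ra (3.47), and of the growth factor receptor Pdgfra (2.90). They had lower levels of Itm2a (-6.11), the imprinted adaptor Grb10 (-5.98), Igfbp2 (-4.87), the adhesion molecule Alcam (-4.75), the imprinted gene Mest (-4.57) and Igf2 (-4.33). In the lines Itm2a (4.30 and 4.19), Grb10, Alcam and Mest lay below the array medians, so these sizes are approximate. Of 12676 genes 39 were at least 4-fold higher and 144 lower in both lines, 183 together, and 463 without BLS4 and 385 without BLS12. A limma fit that assumed the MEF array to vary like the lines called 30.

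Imprinted growth genes had 5 of 12 members 4-fold lower (median -2.18, percentile 0.0) and perivascular and contractile genes 7 of 16 (-1.66, 0.0), including Mcam, Actg2 and Tagln. Myeloid markers had 5 of 14 lower (-1.98, 0.0), Schwann and neural markers 2 of 6 (-1.57, 0.04) and endothelial markers 2 of 8 (-0.91, 0.08). Complement had 2 of 14 higher and 2 lower (0.85, 100); the lower ones were the C1q chains C1qb and C1qc, which macrophages express. Medians were positive for chemokines (0.45), cytokines (0.53) and interferon-stimulated genes (0.56), each at percentile 100, and negative for cell cycle genes (-0.51, 0.0) and collagens (-0.32, 0.02). Ccl19 was at 6.04 in both lines and 6.08 in MEF. Of the T zone markers, 0 of 7 differed by 4-fold (-0.29, 6.38).

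Fresh LN stroma was set against the unstimulated lines to show which transcripts separated them. LN stroma had higher levels of Inmt by at least 8.19 log2 units, Lepr by 7.85, Cxcl13 by 7.70, Lum by 7.69, C7 by 7.49, the interferon-inducible chemokine Cxcl10 by 7.25 and the pericyte marker Rgs5 by 6.93. In the lines most of these lay below the array medians of 5.74 and 5.69, as Lepr at 3.91 and 3.70 and Inmt at 4.27 and 4.13, so their sizes and order are approximate too. Secretory gland transcripts were again among the 15 largest, with Bpifa2 at 7.35, Amy1 at 6.87 and the pancreatic protease Cpb1 at 6.53. The lines had higher levels of the hyaluronan-binding protein Cemip (-4.56), the NKG2D ligand H60b (-4.14), the interferon-inducible Ifi202b (-4.08), Ctla2a (-3.83), S100a4 (-3.41) and the receptor Met (-3.09). Of 12827 genes 451 were at least 4-fold higher and 73 lower than in both lines, 524 together. Without BLS4 640 were higher and 341 lower (981), and without BLS12 577 and 185 (762), so the balance depended on passing in both lines. The array median of LN stroma lay 0.12 above that of BLS12 and 0.06 above that of BLS4. Without pancreatic and salivary transcripts, chosen after seeing the data, 426 were higher and 73 lower.

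Dissociation stress genes had 20 of 25 members 4-fold higher in LN stroma (median 3.56, percentile 100). T zone reticular cell markers had 6 of 10 (4.32, 100), with Ccl19 at 12.49 against 6.04 in the lines and Il7 at 9.13 against 3.89 and 4.10. Chemokines had 9 of 19 higher (2.77, 100), follicular dendritic and marginal reticular cell markers 5 of 10 (2.25, 100), including the complement receptor Cr2, complement 5 of 12 (1.75, 100), cytokines 9 of 19 (1.61, 100), antigen presentation 4 of 15 (1.26, 100) and the NF-κB pathway 5 of 21 (1.13, 100). Collagens had 5 of 35 higher and 3 lower (0.88, 100). Cell cycle (-1.61, 0.0) and cholesterol synthesis (-1.55, 0.0) had negative medians, each with 1 member 4-fold lower. Endothelial markers had 3 of 14 higher (0.89, 99.71), and the 5 lymphocyte markers above the filter, of 17 with an entry, had 0 (0.66, 96.56), with Ptprc, the gene of CD45, at 5.70 in LN stroma. Medians of perivascular genes (0.07) and matrix proteases (-0.03) changed sign with the scaling.

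**Figure D5:**
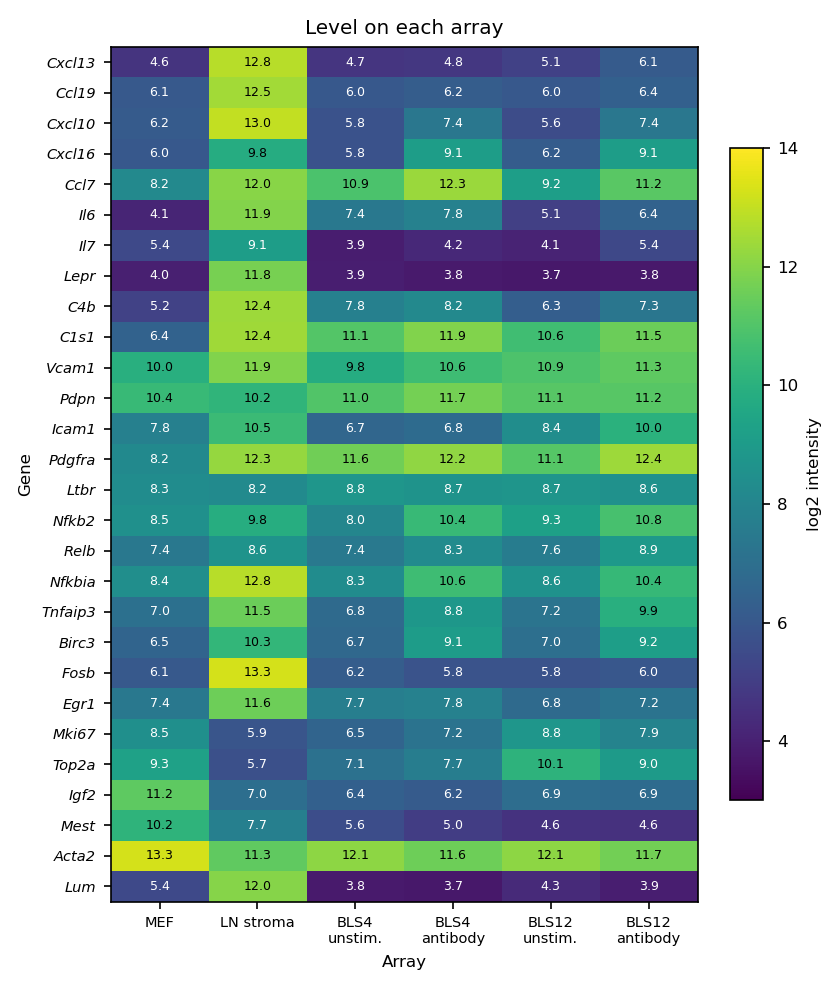
Log2 intensity of 28 genes in the 6 arrays, 1 column per array, coloured from dark for low to yellow for high intensity. Cxcl13 and Ccl19 stood at 12.82 and 12.49 in LN stroma, while Ccl19 lay between 6.04 and 6.39 in the cell lines.

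Some differences from MEF were shared by LN stroma and both lines. All 3 LN-derived arrays exceeded MEF in Xdh by at least 5.25 log2 units, Lpl by 4.19, C1s1 by 4.18, the selenium carrier Selenop by 3.65, C1ra by 3.47 and Pdgfra by 2.90. They lay below MEF in Crabp1 (-4.52), Igfbp2 (-4.32), Igf2 (-4.28), Nes (-4.05) and Alcam (-3.92). Of 13065 genes 27 were at least 4-fold higher and 92 lower in all 3, where independent lists would share 1.7 and 4.1. Unchanged groups sharing the MEF array shared 0.01 and 0.02 in simulation. That simulation used the residual spread of the cell line model, which is small against 4-fold, so almost no overlap could arise. Larger deviations of the MEF array were not simulated. Across genes the covariance of the LN and cell line differences was 0.339 and in the simulation 0.024, while r was 0.437 and in the simulation 0.578. The MEF array stood on both sides and could not be split, so its own deviations entered all of these values. Leaving out BLS4 or BLS12 each gave 201 genes in place of 119. Imprinted growth genes had 3 of 12 lower in all 3 arrays (median -1.93, percentile 0.0), perivascular genes 5 of 16 (-1.35, 0.0) and myeloid markers 3 of 14 (-1.82, 0.0). Complement had 2 of 14 higher and 2 lower in all 3 (median 1.70), chemokines 0 of 20 (1.64) and dissociation stress genes 0 of 25 (1.05), each at percentile 100. These medians average the 3 differences: against MEF, chemokines lay at 3.75 in LN stroma and 0.45 in the lines, and stress genes at 3.41 and -0.02.

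The last comparison asked whether the LTβR antibody moved the lines toward fresh LN stroma. The antibody difference of 1 line was set against LN stroma minus the other unstimulated line, so that no array stood on both sides. Of the 24 genes that rose with antibody 23 were higher in LN stroma than in both unstimulated lines, with Cxcl10 7.25 and Rarres2 4.89 above BLS4. Dclk1 was only 0.01 above BLS4, less than the shift of 0.06 between those array medians. Of the 9 that fell, 4 were lower in LN stroma than in both lines (Scg2, Ctla2a, Cnn1 and Cav1) and 4 were higher (Kcne4, Aoc3, Sfrp2 and Ogn). These counts used the same unstimulated arrays on both sides. Among 12609 genes, those at least 2-fold apart with antibody in BLS4 had the same sign as LN stroma minus BLS12 in 118 of 193 (61.1%), and those in BLS12 as LN stroma minus BLS4 in 296 of 462 (64.1%). Of the rises 92 of 118 and 142 of 197 were higher in LN stroma, and of the falls 26 of 75 and 154 of 265 were lower. Over all genes 44.0% and 43.3% were higher in LN stroma. Dissociation stress genes, with a median of 3.56 above the lines, were high in the same LN stroma array. Across genes r was -0.013 (covariance -0.0049) for BLS4 and 0.18 (covariance 0.0822) for BLS12. Genes are not independent replicates, and LN stroma had 1 array.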

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

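The tests of a uniform response, of noise in the cell cycle genes, of mesothelial identity and of other epithelial cells, the comparison of list medians line by line, and the search of list members for opposite signs, were chosen only after the result was seen. The salivary, pancreatic, noise and scaling tests were set beforehand, but for all of these tests the bounds (one-sided, each at 95% confidence), and for the salivary, pancreatic and mesothelial lists the removal of members seen earlier, were added after the values were known. The ratio of 1.38 for the antibody differences had been seen before the noise and scaling tests were run. Bounds of ratios came from 1000 resamplings of genes, which are not independent replicates, and do not cover variation between repeated arrays.

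The LN stroma array held pancreatic transcripts at high levels, led by Ctrb1 (11.13 log2 intensity), Cpa1 (10.98), Cpb1 (10.5), Ctrl (10.2) and Try5 (9.97). A few salivary transcripts were also high, namely Bpifa2 (11.84), Amy1 (10.55) and Smr3a (8.06). Car6 (6.93) and Pip (6.25) were also at least 4-fold above each other array but lay below the 75th percentile of LN stroma, 7.70. The same held for some pancreatic transcripts, such as Dmbt1 (6.71) and Try4 (6.31). Of 24 pancreatic acinar transcripts not seen before that list was written, 19 (79.2%, bounds 61.1 and 91.4) were at least 4-fold above each other array, against 1.63% of all genes, as were 20 of 25 (80%) in the whole list, so pancreatic RNA or cells in the sorted fraction may be a source. Of 19 salivary transcripts not seen before, 3 (15.8%, bounds 4.4 and 35.9) met that size, and 5 of 21 (23.8%) in the whole list; 15.8% lay under the limit of 20% first set against this source and 23.8% above it, so a salivary source stays open. Aqp5 was at 6.76 in LN stroma and between 6.64 and 7.0 elsewhere, and Amy1 may share signal with pancreatic amylases. The sort for cells without CD45 and CD31 and with podoplanin and VCAM-1 should remove acinar cells, cells and free RNA were not told apart, and expression of these transcripts by LN stroma itself was not tested.

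Antibody differences were larger in BLS12 than in BLS4, with a ratio of their SDs of 1.38. Scaling between the BLS12 arrays as the whole cause was argued against, since the ratio stayed at 1.35 (bounds 1.31 and 1.4) after quantile normalization. In 7449 genes below the array median on all 4 arrays the ratio was 1.15 (bounds 1.12 and 1.18; SD 0.221 against 0.193), between the values set for and against more array noise in the BLS12 pair and measured near the floor, so noise may account for part of it. Among the 80 genes at least 2-fold apart in both lines, the median ratio of the BLS12 to the BLS4 difference was 1.1 (bounds 0.99 and 1.2), and 45 were larger in BLS12; the value alone met the limit set against a uniformly larger response, but its bounds did not. Noise independent from gene to gene was argued against for the cell cycle genes, of which 34 of 34 were negative in BLS12. This was 100% (lower bound 91.6), against 56.4% of all genes. These genes may vary together, so a shift they share between single cultures could not be told from a response to antibody. For the other genes noise and a response that differs between the lines could not be told apart with 1 array per line and condition.

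BLS12 had higher levels of transcripts known from mesothelium, among them Gpm6a (6.19 log2 units), Pkhd1l1 (4.90), Bnc1 (4.61), Lrrn4 (4.06), Upk3b (3.06), Nkain4 (2.59), Crb2 (1.66) and Cyp2s1 (1.51). Each of these was lower in antibody-treated than in unstimulated BLS12, as Gpm6a (9.79 against 11.77) and Upk3b (8.61 against 10.17). Each stood above MEF in both BLS12 arrays. Upk1b and Krt19, also called higher in BLS12 than in BLS4, stood higher in MEF (9.21 and 8.72) than in unstimulated BLS12 (7.96 and 7.45). Transcripts of other epithelial cells were not raised in BLS12. Of 15, 0 (0.0%) were at least 2-fold higher there in either condition, against 5.1% of all genes. Most were dim, and the test was first run as 0 of 5 tested genes. Members seen earlier, among them Epcam, Cdh1, Cldn3 and Cldn4, stayed in this list, unlike in the pancreatic, salivary and mesothelial lists. The test therefore cannot decide against such cells by the 20% limit. The one-sided upper bound of 18.1% lay under the limit of 20% and a two-sided one (21.8%) above it, both far below the 50% that such cells would need. Of 9 mesothelial transcripts not seen before that list was written, 3 (33.3%, bounds 9.8 and 65.5) were called higher in BLS12, against 12.2% of all genes, and 12 of 21 (57.1%) in the whole list, 12 members of which had been seen. Mesothelial identity of BLS12 cells is a hypothesis that these values leave open, with Krt7 (0.02), Krt8 (0.25) and Krt18 (0.25) short of the threshold and Sulf1 (-0.80) lower in BLS12, as they do the origin of the lines, which was not tested.

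Antibody differences had opposite signs in the lines, each beyond 0.43 log2 units, in 98 of the 11988 genes, among them 22 list members, 11 of these in the cell cycle list, and these differences between the lines were not tested. Peg10 was at -0.62 in BLS4 and 1.09 in BLS12. Lyz2 was at -0.70 in BLS4 and 1.81 in BLS12, and its near-identical paralog Lyz1 at -0.47 and 0.92. The other 8 list members lay outside the rule for naming genes of this comparison. In BLS4 and BLS12, Jag1 was at -0.66 and 1.1, Hgf at -0.50 and 0.89, Pdgfrb at -0.46 and 0.61, Tnxb at -0.56 and 1.71, and Mmp11 at -0.75 and 0.78, while Lif was at 0.96 and -0.43, Cd59a at 0.52 and -0.49, and Fmod at 0.83 and -0.49. Cell cycle genes had a median of 0.36 in BLS4, where 32 of 34 were positive, and -0.85 in BLS12, where 0 were positive, at percentiles of 100 and 0.0 among random lists. Among entries outside the named genes, 3 with several genes (2 up, 1 down) and 28 with no gene (25 up, 3 down) differed at least 2-fold in the same direction in both lines, while the median antibody difference of entries with no gene was 0.01 in BLS4 and 0.09 in BLS12.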

How the results depend on the processing

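The list counts under each scaling, the line differences of lists in each condition alone and the counts without gland transcripts were chosen only after seeing the data. No called list, and none of the 33 genes called with antibody, reversed its direction under any setting run, but the larger side of some counts did. Some named genes short of the antibody threshold reversed when 1 line was left out. Peg10 was at -0.62 in BLS4 and 1.09 in BLS12, and Lyz2 at -0.70 and 1.81. Between the lines, Lyz2 was lower in unstimulated BLS12 than BLS4 (7.82 against 8.54) and higher with antibody (9.63 against 7.84). The antibody count of 33 became 0 without the cell line as a block (limma, 1396 genes at an unadjusted p under 0.05 with the block), 54 without a filter, 123 with the filter at the 75th percentile, where 22 of the 33 were tested and all passed, 6 after quantile normalization and 98 after centring. It was 45 with an intensity trend and 33 with the mean of a gene's entries or all 6 arrays in the fit. The 2835 genes between the lines became 1428 without the antibody as a block (670 higher and 758 lower in BLS12, against 1467 and 1368) and 2791 after quantile normalization (1308 and 1483), and otherwise ranged from 2283 to 2895. The 8 lists became 1 with fry, 8 after quantile normalization and 11 after centring. With an estimated correlation they became 0, in a test with 1 residual degree of freedom and little power. The cause of the other changes in these counts was not tested. Of 174 named antibody differences, 27 lost their call after quantile normalization and 33 without the block, and 21 gained one after centring.

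Looser sizes gave more genes by construction. At 1.5-fold in both lines the 80 became 303. At 2-fold, LN stroma against MEF gave 2815 (1292 higher, 1523 lower) in place of 955 (585 and 370), the lines against MEF 738 in place of 183, LN stroma against the lines 1447 in place of 524, and the shared genes 452 in place of 119. Leaving out a line dropped the need to pass in both: 188 to 447 genes with antibody (192 higher and 255 lower without BLS4, against 52 and 28), 385 to 463 for the lines against MEF, 762 to 981 for LN stroma against the lines, and 201 in both cases for the shared genes. The antibody test itself had no residual degree of freedom without a line. A limma fit with the spread between lines standing for the lone array gave 30 genes for the lines against MEF and 449 for LN stroma against the lines. With the same unstimulated array on both sides, the shares of equal sign rose from 61.1% to 72.5% and from 64.1% to 76.4%, as that array then enters both differences. Without gland transcripts 930 and 499 genes remained of 955 and 524. Dim transcripts near the array median, and the number of arrays, limit what could be detected.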

Other observations

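The groups of genes in the next paragraphs, and their order, were chosen only after seeing the data. Some transcripts set both cell lines, with and without antibody, apart from both C57BL/6JJcl arrays. Ifi202b, an interferon-inducible gene, was the 1 gene at least 4-fold higher in all 4 cell line arrays than in MEF and LN stroma, with a gap of 3.67 log2 units between the nearest arrays. In the other direction 33 genes were at least 4-fold lower. Itm2a, a membrane protein, stood between 4.18 and 4.30 in the lines and at 10.41 in MEF and 10.35 in LN stroma. Ptn, the growth factor pleiotrophin (gap 4.51), Grb10 (4.23), Tenm3 (4.08), the protease Ctsc (4.03), the heparan sulphate proteoglycan Gpc3 (3.67) and Igfbp5 (3.42) followed. Des, which encodes desmin, was at 8.21 in MEF, 11.12 in LN stroma and between 5.21 and 5.69 in the lines, and Ptgs2, the inducible cyclooxygenase, at 11.94, 13.21 and between 9.0 and 9.73. Strain and establishment as a line were not separated by the design.

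Median antibody differences of some lists differed in size between the lines, without a test of the difference. Chemokines had a median of 1.51 log2 units in BLS4 and 0.54 in BLS12, and cholesterol synthesis -0.45 and -0.95. The NF-κB pathway lay at 0.84 and 0.83, and collagens at -0.40 and -0.45. Complement had 0.40 with 9 of 11 positive in BLS4 and 0.21 with 7 positive in BLS12. In glycolysis and hypoxia genes 16 of 17 were positive in BLS4 and 6 in BLS12, with medians of 0.17 and -0.16. Follicular dendritic and marginal reticular cell markers lay at -0.07 in BLS4 and 0.62 in BLS12.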
